A study of Arabidopsis thaliana with 36 samples.

How the data were processed

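RNA of green leaf tissue from 36 samples of 14-day-old Arabidopsis seedlings had been labelled and hybridised to one-colour Affymetrix ATH1 arrays, 1 sample per array. The intensities had been summarised and normalized across arrays by the authors before they were deposited, on a linear scale. The processing notes name RMA and GCRMA without versions, and which of them made the values is not stated. Deposited values ran from 2.096 to 54591, with array medians from 77.7 to 83.6 and upper quartiles from 373.4 to 385.6. Lower quartiles ran from 5.48 to 5.9, or 2.45 to 2.56 in log2. Raw array files and detection calls were not used here.

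Values were converted to log2. Of 22810 probe sets deposited, 64 control probe sets were left out and 22746 were tested. A probe set was given a gene name where the gene table listed 1 gene for it, which held for 13513 probe sets and 13286 loci. The table listed several genes for 503 probe sets and had no entry for 8730, and these were tested and counted but not named. ANAC017, ANAC016, ANAC013 and AOX1A had no probe set in the table, so the ANAC017 transcript and these genes were not analysed here.

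Arrays were grouped by genotype and spray as labelled, with 3 arrays in each of 12 groups. Group means were fitted to all 36 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 24 residual and 1.28 prior degrees of freedom). From the fit came 17 contrasts: each spray against water in each genotype, each mutant against wild type in water, and the difference between each mutant and wild type in each response. Probe sets were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. The ± beside a log2 change is the standard error of this fit, and the ± beside a level is the SD of 3 arrays. The standard error rests on 1 residual variance per probe set over all 12 groups. It therefore does not measure the spread within a single group.

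A value at or below the lower quartile of its array was taken as not above background, a limit set after the results were seen. Of 166 named probe sets, 40 had 2 or 3 arrays so low in at least 1 group. Their changes were computed again with each such value raised to the quartile, without a new test. With such values on both sides of a comparison the result is neither exact nor a bound. The list members EXPA7, NDB3, GSTU28, GH3.1 and CLV3 were so low on all 36 arrays. Without EXPA7 the root markers keep 2 members, so their list test was not used.

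The contrasts, the alternatives, the rule for named genes and 27 gene lists were chosen before the data were examined. The rule took 10 risen and 6 fallen genes for each response in wild type, 5 higher and 5 lower for each mutant in water, 8 genes called with the same sign in rao2 and anac017-1 for the differences, and 4 highest and 4 lowest for anac017-2. Genes named for the wild type responses and for mutants in water had to be called, with all values of 1 group beyond all of the other. The rule also took up to 4 called members of each list, or the 2 with the lowest p. Each list used the probe set with the highest mean for a locus. Of the lists, 15 with at least 3 measured loci were tested with limma camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data. Lists overlap in members such as AT2G21640, NDB4 and AT2G04050. They were written from general knowledge of such responses, so whether these arrays helped to define the stimulon list is not known.

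Measured over listed loci were 5 of 12 for the alternative respiratory pathway, 9 of 22 for the mitochondrial dysfunction stimulon, 14 of 27 for oxidative phosphorylation, 0 of 17 for mitochondrial carriers and import, 8 of 26 for heat shock, 5 of 10 for the reactive oxygen hallmark and 8 of 31 for antioxidant enzymes. They were 8 of 29 for glutathione transferases, 5 of 19 for glycosyltransferases and detoxification, 4 of 27 for WRKY and 1 of 28 for NAC factors, 2 of 17 for salicylate, 2 of 24 for jasmonate, 0 of 19 for ethylene and 1 of 13 for tryptophan and camalexin. The others were 2 of 21 for abscisic acid, 4 of 16 for auxin, 2 of 15 for hypoxia, 3 of 17 for the unfolded protein response, 9 of 43 for photosynthesis, 2 of 18 for glucosinolates and 4 of 15 for flavonoids. Cell division had 3 of 21, the clock 1 of 16, root markers 3 of 21, guard cell markers 1 of 7 and shoot meristem markers 1 of 6.

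The share of the wild type response kept in a mutant was the median, over probe sets called in wild type with an absolute log2 change of at least 1, of the mutant change over the wild type change. Overlaps of calls were set beside the number for independent lists and beside 100 simulations of unchanged groups that shared their reference arrays. Calls were also counted in 10 splits of the 6 arrays of a contrast of 2 groups, and in 100 splits for each difference of responses.

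The fit was tested on simulated data with the spread of these arrays. Of simulated changes of 1 on the log2 scale, 63% to 82% were called, and of changes of 2, 85% to 98%, with 6 to 13 false calls. Of 50 simulated lists, the 5 shifted were called and 0 others. The simulated probe sets varied independently, so this does not test the list calls where genes are correlated. Alternatives were quantile normalization, a filter on dim probe sets, an intensity trend with a robust prior, array weights, the replicate number as a block, a fit of only the groups compared, each array left out in turn, a stricter adjusted p of 0.01 for overlaps and a change of at least 2 for the share kept.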

Results

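The data were 36 one-colour arrays of RNA from green leaf tissue of 14-day-old Arabidopsis seedlings. Seedlings of 4 genotypes were sprayed with water, 50 µM antimycin A (an inhibitor of mitochondrial complex III) or 20 mM hydrogen peroxide, and tissue was taken 3 h later. Each of the 12 combinations had 3 arrays. The genotypes were wild type (labelled Col:LUC), rao2 (a line from chemical mutagenesis), anac017-1 (an insertion line described as a knock-out) and anac017-2 (described as gain of function). Only wild type has the Col:LUC label, and whether the mutants carry the same reporter or rao2 was backcrossed is not stated. Every difference between a mutant and wild type below may therefore include a difference of genetic background. The comparisons ask how far the transcript responses to the sprays depend on the NAC transcription factor ANAC017. The targeted gene ANAC017 had no probe set with a gene name in the gene table, and neither did ANAC016, ANAC013 or the alternative oxidase AOX1A. The ANAC017 transcript was therefore not analysed here and gave no check of the genotype labels.

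The median deposited intensity lay between 77.7 and 83.6 on every array, and replicate arrays of a group correlated across probe sets with r between 0.983 and 0.997. Genes are not independent replicates, so these correlations describe the arrays only. The lower quartiles of the arrays lay between 2.45 and 2.56 (log2), and a value at or below that of its array was taken as not above background. Where 2 or 3 arrays of a group were so low its level was not measured, and changes that used it were computed again with such values raised to the quartile (raised values). With all low values in 1 group the raised change is a lower bound on the size of the change, written as at least. The limma tests used the values as deposited. Principal component 1 held 56.3% of the variance. The antimycin A arrays of wild type (mean -95.8 ± 13.7, SD, n = 3), rao2 (-96.7 ± 14.3) and anac017-1 (-108.7 ± 10.4) lay far from the water arrays, whose group means lay between 39.3 and 49.4. The antimycin A arrays of anac017-2 had a mean of 22.8 ± 8.3 and lay near the hydrogen peroxide groups, with means from 12 to 34.6. The signal at the 3' end minus that at the 5' end of the actin, GAPDH and ubiquitin controls averaged 3.14 ± 0.17 (log2, SD, n = 3) in wild type water arrays, 3.27 ± 0.04 in anac017-1 water arrays and 3.48 ± 0.20 in anac017-1 antimycin A arrays. The number of arrays limits the precision of every value. The origin of the replicates is not stated, so the p-values measure the spread between these samples.

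**Figure D1:**
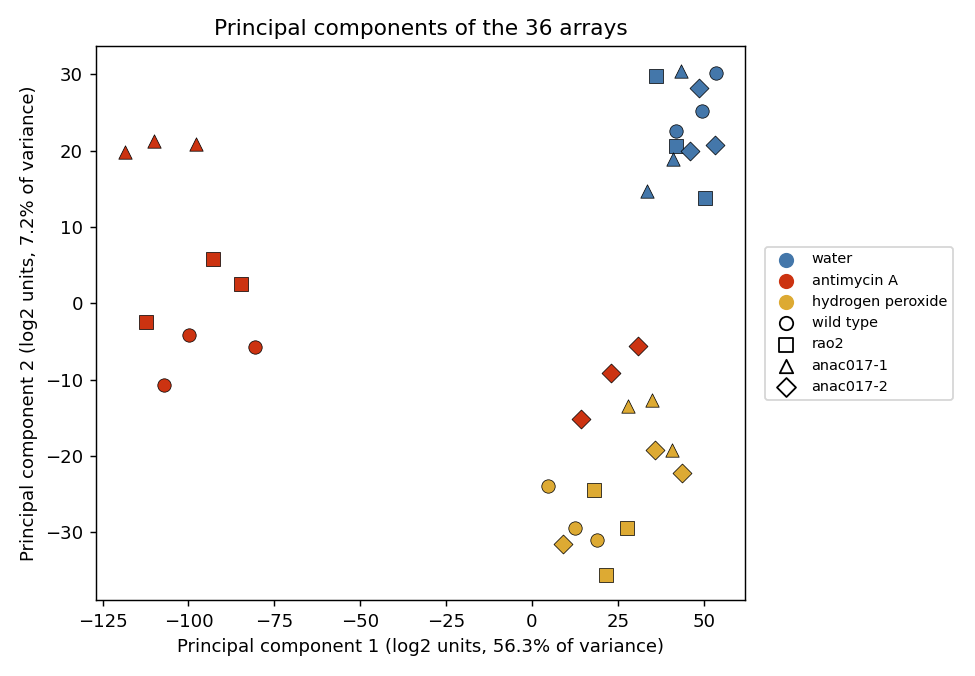
Scores of the 36 arrays on principal components 1 (56.3% of variance) and 2, in log2 units; colours mark the spray and shapes the genotype. The antimycin A arrays of wild type, rao2 and anac017-1 lie between -118.4 and -80.6 on component 1, and those of anac017-2 between 14.3 and 31.

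Antimycin A in wild type raised a broad set of stress transcripts. AT2G32020, which encodes an acetyltransferase-like protein, rose by at least 9.27 (9.70 ± 0.71 in the fit; log2, SE of the limma fit, n = 3 per group, as for all changes below). AT4G39670, encoding a glycolipid transfer protein, rose by 9.18 ± 0.68, ZCF37 by 8.47 ± 0.74 and AT2G23270 by 8.10 ± 0.80. AT4G28460 rose by 7.91 ± 0.68, AT1G22810 (an ethylene response factor) by 7.83 ± 0.49, AT4G28085 by 7.69 ± 0.72 and AT3G26470 by 7.18 ± 0.66. AT3G01830 (a calmodulin-like protein) rose by 7.03 ± 0.95 and AT2G04050 (a multidrug transporter) by 6.97 ± 0.95. AT5G62210 fell by 5.48 ± 0.39, AT5G01790 by 5.16 ± 0.71 and the chalcone isomerase-like gene CHIL by 5.07 ± 0.55. AT4G28780 (-5.01 ± 0.33), AT3G23450 (-4.85 ± 1.2) and AT3G17050 (-4.28 ± 0.55) fell as well. In water AT4G39670, AT2G23270, AT1G22810 and AT3G26470 were, like AT2G32020, not above background, so they rose by at least 8.9, 7.98, 7.52 and 6.91. Under antimycin A the same held for AT5G01790, CHIL, AT4G28780 and AT3G17050, so that their raised changes were -4.79, -4.31, -4.75 and -3.79. All 16 had adjusted p of 0.0015 or less in limma. Antimycin A values beyond all water values were a condition for naming these genes, so that separation adds no support. Any unchanged probe set with 3 arrays against 3 meets it with a chance of 10%.

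Genes of the mitochondrial dysfunction stimulon, which respond to disturbed mitochondria, rose together under antimycin A: 9 of the 9 measured were called (9 adjusted over the list alone). AT2G32020 was among them, AT2G04070 rose by 6.88 ± 0.73 and AT2G21640 by 5.14 ± 0.49. The external NAD(P)H dehydrogenase NDB4, not above background in any water array, rose by at least 3.91 (4.61 ± 0.28 in the fit). The limma camera test of this list gave adjusted p = 6.41e-09, and adjusted p = 0.0497 with an estimated correlation. All 5 measured reactive oxygen hallmark genes rose (5 adjusted over the list alone), among them AT1G05340 by 5.34 ± 0.51 and the zinc finger gene STZ by 3.59 ± 0.34. The camera adjusted p was 1e-05, and adjusted p = 0.0131 with an estimated correlation. All 5 measured glycosyltransferase and detoxification genes rose (5 adjusted over the list alone), including UGT73B4 by 5.73 ± 0.55 and UGT73B5 by 3.82 ± 0.29. Here camera gave adjusted p = 8.29e-05, and adjusted p = 0.0279 with an estimated correlation.

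Other groups had called members under antimycin A without a called list. In the alternative respiratory pathway, NDB4 and NDB2 (2.65 ± 0.27) rose, NDB1 (-0.78 ± 0.18) and NDC1 (-0.18 ± 0.06) fell and NDB3 was not above background on any array (adjusted p of the list 0.194; 4 adjusted over the list alone). Among 14 nuclear subunits of oxidative phosphorylation, 8 fell, such as AT3G15640 (-1.22 ± 0.19) and AT1G51980 (-0.81 ± 0.07), and 2 rose, CYTC-2 (0.40 ± 0.11) and SDH2-1 (0.34 ± 0.11), with a list adjusted p of 0.0601 (11 adjusted over the list alone). All 3 cell division genes fell: PRL (-2.63 ± 0.37), AUR2 (-1.93 ± 0.50) and AUR1 (-1.71 ± 0.39), with a list adjusted p of 0.0993 (3 adjusted over the list alone). Of 8 glutathione transferases, 4 rose, led by GSTU22 (5.90 ± 0.70) and GSTU25 (4.73 ± 0.91), and 2 fell (list adjusted p 0.29; 7 adjusted over the list alone). WRKY6 (2.77 ± 0.26) and WRKY22 (1.57 ± 0.35) rose among 4 WRKY genes (0.0601; 2 adjusted over the list alone). GH3.3 (3.63 ± 0.44) and WES1 (1.89 ± 0.26) rose among 4 auxin response genes (0.086; 2 adjusted over the list alone). GSTU28 of the glutathione transferases and GH3.1 of the auxin list were, like NDB3, not above background on any array. BZIP60, a transcription factor of the endoplasmic reticulum unfolded protein response, rose by 3.39 ± 0.21 and BZIP28 by 0.90 ± 0.11, while ATERDJ3B fell by 1.61 ± 0.19 (0.169; 3 adjusted over the list alone).

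Of 8 heat shock genes, AT5G37670 (2.68 ± 0.52) and AT5G51440 (1.59 ± 0.48) rose and AT3G09440 (-1.32 ± 0.22) fell under antimycin A, with a list adjusted p of 0.538 (3 adjusted over the list alone). The antioxidant enzymes had 1 risen and 4 fallen members of 8 (0.49; 6 adjusted over the list alone), including AT3G52960 (-0.98 ± 0.13). Photosynthesis had 3 fallen of 9 (0.538; 1 adjusted over the list alone), among them ATPC1 (-0.51 ± 0.10). Flavonoid synthesis had 1 fallen of 4 (0.538; 1 adjusted over the list alone), UGT78D2 (-0.90 ± 0.17). Of the root markers EXPA7 was not above background on any array, which left 2 members, of which 0 were called by limma with 0 at an unadjusted p under 0.05. Lists with fewer than 3 measured members had no list test, and that of the root markers was not used. In these, GRX480 of the salicylate list rose by 5.55 ± 0.71, and NAC014 of the NAC list (-0.36 ± 0.09), AT4G10270 of the hypoxia list (-3.69 ± 1.13), AT2G31790 of the glucosinolate list (-1.12 ± 0.20) and the guard cell marker FMA (-0.93 ± 0.17) fell. Uncalled members were JMT (-0.46 ± 0.68) and PDF1.2 (-1.08 ± 0.87) of the jasmonate list, COR47 (0.60 ± 0.33) and COR15A (-0.07 ± 0.76) of the abscisic acid list, AT2G04400 of tryptophan synthesis (0.58 ± 0.26), the clock gene GI (-0.35 ± 0.16) and the meristem marker CLV3 (0.10 ± 0.05), which was not above background with either spray. The ethylene list and the list of mitochondrial carriers had 0 measured members.

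In all, limma called 10002 of 22746 probe sets for antimycin A in wild type, 3923 risen and 6079 fallen. Of these, 2058 rose and 1902 fell by at least 1 on the log2 scale. Leaving out single arrays gave 8933 to 9849 calls. The call of AT5G51440 was lost without wild type antimycin A replicate 3, and that of NDC1 without wild type antimycin A replicate 2 or water replicate 1 or 2.

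Hydrogen peroxide in wild type raised heat shock transcripts strongly. A probe set without a gene in the table had a rise of 7.35, and the values below are of probe sets with 1 gene. The small heat shock gene ATHSP22.0 rose by 6.55 ± 0.39, the chaperone gene AT1G71000 by 6.02 ± 0.80, HSA32 by 5.11 ± 0.56 and AT1G53540 by 5.01 ± 0.44. AT1G52560 rose by 4.93 ± 0.35, AT5G37670 by 4.89 ± 0.52, AT1G72660 by 4.6 ± 0.38 and AT1G54050 by 4.45 ± 0.32. AT4G39670 rose by 6.21 ± 0.68 and AT2G32020 by 4.92 ± 0.71. The named falls were AT3G17050 (-3.14 ± 0.55), AT1G75960 (-2.74 ± 0.65), AT5G48430 (-2.60 ± 0.46), AT5G64110 (-2.47 ± 0.39), AT4G16563 (-2.40 ± 0.55) and AT5G62210 (-2.36 ± 0.39). In water ATHSP22.0, HSA32, AT4G39670 and AT2G32020 were not above background, so they rose by at least 6.5, 4.59, 5.92 and 4.49, and AT1G75960, so low under hydrogen peroxide, had a raised change of -2.51. All 16 had adjusted p of 0.0049 or less in limma, and hydrogen peroxide values beyond all water values were again a condition for naming them.

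Of 8 measured heat shock genes, 7 rose under hydrogen peroxide (7 adjusted over the list alone), and AT3G09440 was not called (0.33 ± 0.22). The camera test gave adjusted p = 6.49e-16, and adjusted p = 0.00138 with an estimated correlation. All 5 reactive oxygen hallmark genes rose (5 adjusted over the list alone), such as AT1G05340 (3.23 ± 0.51) and AT2G21640 (2.83 ± 0.49). Their camera adjusted p was 1.47e-07, and adjusted p = 0.00138 with an estimated correlation. In the mitochondrial dysfunction stimulon 5 of 9 rose (7 adjusted over the list alone), with AT2G41730 (2.82 ± 0.59) and AT5G43450 (2.07 ± 0.39) among them, and NDB4 was not above background (0.06 ± 0.28). Camera gave adjusted p = 6.59e-07 for this list, and adjusted p = 0.0792 with an estimated correlation.

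UGT73B4 (2.17 ± 0.55) and UGT73B5 (1.27 ± 0.29) rose among 5 glycosyltransferase and detoxification genes under hydrogen peroxide (4 adjusted over the list alone), with adjusted p = 0.00367, and adjusted p = 0.0792 with an estimated correlation. BZIP60 (1.2 ± 0.21) and BZIP28 (0.59 ± 0.11) rose among 3 unfolded protein response genes (2 adjusted over the list alone), with adjusted p = 0.0321, and adjusted p = 0.0792 with an estimated correlation. GSTU16 (1.08 ± 0.13) and GSTU18 (0.71 ± 0.22) rose among 8 glutathione transferases (2 adjusted over the list alone), with adjusted p = 0.038, and adjusted p = 0.091 with an estimated correlation. AUR2 (-1.53 ± 0.50) and AUR1 (-1.41 ± 0.39) fell among 3 cell division genes (3 adjusted over the list alone), with adjusted p = 0.0393, and adjusted p = 0.288 with an estimated correlation. Of the lists without a call, the alternative respiratory pathway held the risen NDB2 (1.21 ± 0.27), and oxidative phosphorylation the risen CYTC-2 (0.66 ± 0.11) and SDH2-1 (0.51 ± 0.11), with a median of -0.07 beside a test direction upward. Its adjusted p was 0.794 (4 adjusted over the list alone), and that of the alternative respiratory pathway 0.327 (1 adjusted over the list alone). The antioxidant list held the risen ATMDAR2 (0.84 ± 0.19) and GR1 (0.59 ± 0.11), with a median of -0.06 beside a test direction upward (adjusted p 0.327; 2 adjusted over the list alone). WRKY6 (0.79 ± 0.26) rose among 4 WRKY genes, whose median was -0.07 beside a test direction upward (0.619; 1 adjusted over the list alone), and its call was lost without any 1 of 5 of the 6 arrays. Photosynthesis (0.0685), auxin response (0.67) and flavonoid synthesis (0.739) had 0 members called by limma and 0 adjusted over the list alone. In the lists without a test, COR47 rose (1.03 ± 0.33) and NAC014 (-0.37 ± 0.09) and FMA (-0.57 ± 0.17) fell. The call of UGT73B4 was lost without wild type hydrogen peroxide replicate 1 alone. That of AUR1 was lost without hydrogen peroxide replicate 1 or water replicate 1 or 2, that of AUR2 without these or hydrogen peroxide replicate 3, and that of GSTU18 without replicate 1 or 3 of either spray.

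For hydrogen peroxide in wild type limma called 3361 probe sets, 1534 risen and 1827 fallen, of which 472 rose and 227 fell by at least 1 on the log2 scale. The count was 2189 without wild type hydrogen peroxide replicate 2 and 2100 without wild type water replicate 1. It was 5244 when limma weighted the arrays by their quality.

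**Figure D2:**
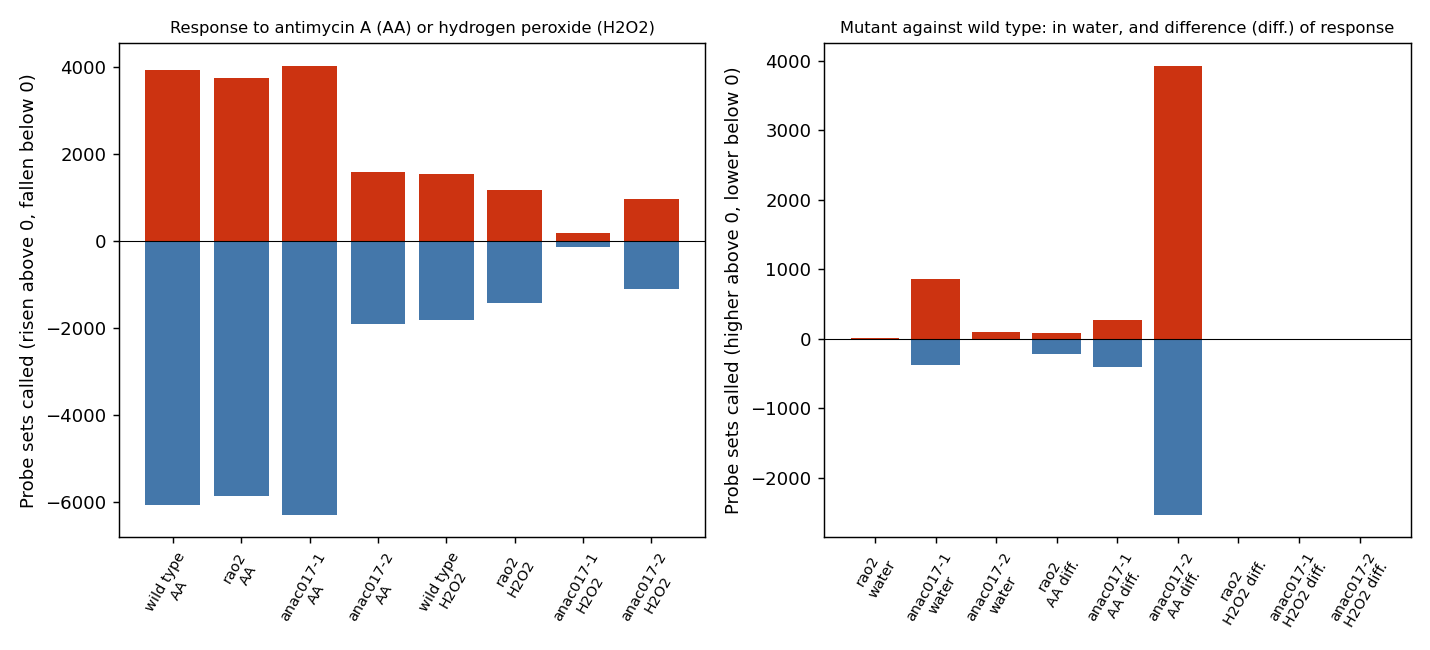
Probe sets called by limma at an adjusted p under 0.05, higher above 0 and lower below 0, for the sprays against water in each genotype (left) and for mutants against wild type in water and in response (right). The differences of hydrogen peroxide response, with 3, 6 and 8 calls, are too few to see at this scale.

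The responses to the sprays in wild type shared AT4G39670, AT2G32020, AT2G21640, STZ and the UGT73B genes named above. Of the probe sets called for either spray, 2722 were called in the same direction for both, 1161 risen and 1561 fallen, and 99 in opposite directions. Independent lists of these sizes would share 264.6 risen and 488.3 fallen probe sets. In 100 simulations of unchanged groups that shared their water arrays, the mean and the highest overlap were 0. Unchanged groups give almost no calls, so this 0 does not measure what shared arrays add to an overlap of calls, here or for the pairs of mutants below. The correlation of the log2 changes across probe sets was 0.66 beside 0.48 in the simulations, and the covariance 0.329 beside 0.026. The 3 water arrays are common to both responses and too few to divide, so part of the excess may come from them. The 2722 were 81% of the hydrogen peroxide calls. At an adjusted p under 0.01 the overlap was 1355.

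Water-sprayed rao2 differed from wild type in few transcripts. AT5G26270 was higher by 4.76 ± 0.61, the orphan gene QQS by 3.13 ± 0.59, AT2G29065 by 1.73 ± 0.32, ETP2 by 1.27 ± 0.09 and AT1G47480 by 1.04 ± 0.16. In wild type AT5G26270, AT2G29065 and AT1G47480 were not above background, so they were higher by at least 4.4, 1.36 and 0.75. AT2G41730, a stimulon gene, was lower (-3.06 ± 0.59), as were AT4G26240 (-2.55 ± 0.26), AT4G19045 (-1.26 ± 0.20), AT5G14550 (-0.97 ± 0.15) and AT5G16860 (-0.61 ± 0.10). AT2G41730 was the only called member of the 9 stimulon genes (2 adjusted over the list alone), whose camera adjusted p was 0.000249, with adjusted p = 0.273 with an estimated correlation. Lists without a called member passed limma camera only at the preset correlation. Photosynthesis passed upward (adjusted p = 0.00876, and adjusted p = 0.298 with an estimated correlation; 0 adjusted over the list alone). Oxidative phosphorylation passed downward (0.0107, and adjusted p = 0.436 with an estimated correlation; 0 adjusted over the list alone). Flavonoid synthesis (0.012, 0 adjusted over the list alone) and auxin response (0.0271, 1 adjusted over the list alone) passed upward, with adjusted p = 0.273 for each with an estimated correlation. Altogether limma called 30 probe sets in rao2, 17 higher and 13 lower. The count was 51 without wild type water replicate 3, 58 without rao2 water replicate 1 and 4 when only the arrays compared were fitted. The call of QQS was lost without rao2 water replicate 3 or wild type water replicate 1 or 2, and that of AT2G41730 without rao2 water replicate 3 or wild type water replicate 2 or 3. That of AT2G29065 was lost without rao2 water replicate 2 or 3 or wild type water replicate 1 or 3.

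Water-sprayed anac017-1 had more raised transcripts, heat shock genes among them. AT1G71000 was higher by 4.40 ± 0.80, AT5G22430 by 4.09 ± 0.43, AT2G20870 by 3.83 ± 0.61, AT1G21550 by 3.80 ± 0.78 and the linker histone gene HIS1-3 by 3.26 ± 0.55. AT3G44970 (-2.21 ± 0.51), AT3G15650 (-1.83 ± 0.53), AT2G41250 (-1.70 ± 0.39), AT5G62210 (-1.61 ± 0.39) and AT4G02850 (-1.61 ± 0.46) were lower. AT5G22430 was not above background in wild type, so it was higher by at least 3.88, and AT3G44970, so low in anac017-1, had a raised difference of -1.88. Of 8 heat shock genes 3 were higher, AT5G37670 (2.81 ± 0.52), AT1G53540 (1.83 ± 0.44) and AT5G48570 (1.38 ± 0.35), with 4 adjusted over the list alone. Camera gave adjusted p = 0.000912, and adjusted p = 0.367 with an estimated correlation. In oxidative phosphorylation 1 of 14 genes was lower, OEP16-3 (-0.30 ± 0.09), with 2 adjusted over the list alone and adjusted p = 0.026, and adjusted p = 0.477 with an estimated correlation. Flavonoid synthesis passed downward at adjusted p = 0.026 with 0 of 4 members called (4 adjusted over the list alone), and adjusted p = 0.367 with an estimated correlation. The glutathione reductase gene GR was higher by 1.26 ± 0.11. The control signal at the 3' end minus the 5' end was 3.27 ± 0.04 in these arrays and 3.14 ± 0.17 in wild type. The total in anac017-1 was 1235 probe sets, 855 higher and 380 lower, but 759 without wild type water replicate 2 and 641 without anac017-1 water replicate 2. The calls of AT3G15650 and AT4G02850 were lost without any 1 of 5 of the 6 arrays, that of OEP16-3 without any 1 of 4 and that of AT5G48570 without any 1 of 3. The call of AT3G44970 was lost without anac017-1 water replicate 2 or 3, that of AT1G53540 without anac017-1 water replicate 3 or wild type water replicate 2, that of AT5G62210 without anac017-1 water replicate 2 and that of AT2G41250 without wild type water replicate 2.

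Water-sprayed anac017-2 had higher levels of stimulon, heat shock and detoxification transcripts. AT1G71000 was higher by 5.02 ± 0.80, AT2G04050 by 4.19 ± 0.95, AT1G21550 by 4.18 ± 0.78, AT5G37670 by 4.17 ± 0.52 and AT2G21640 by 3.64 ± 0.49. AT2G40435 (-1.48 ± 0.34), AT2G43535 (-1.2 ± 0.27), AT4G12540 (-0.96 ± 0.20), AT2G34840 (-0.56 ± 0.13) and AT4G16850 (-0.56 ± 0.12) were lower. Of 9 stimulon genes 4 were higher (7 adjusted over the list alone), AT2G41730 (3.02 ± 0.59) and AT5G43450 (2.13 ± 0.39) besides those above, with camera adjusted p = 2.97e-17, and adjusted p = 0.00315 with an estimated correlation. Of 8 heat shock genes 5 were higher (6 adjusted over the list alone), with AT5G51440 at 2.49 ± 0.48 and AT1G53540 at 2.15 ± 0.44, and adjusted p = 1.06e-15, or adjusted p = 0.00157 with an estimated correlation. UGT73B5 (2.06 ± 0.29) and AT2G04050 were higher among 5 detoxification genes (5 adjusted over the list alone), with adjusted p = 1.85e-13, or adjusted p = 0.000121 with an estimated correlation. Reactive oxygen hallmark genes (1 of 5 called, AT2G21640, 2 adjusted over the list alone) passed at adjusted p = 0.0026, with adjusted p = 0.0567 with an estimated correlation. Oxidative phosphorylation downward (0 called, 0 adjusted over the list alone) passed at adjusted p = 0.00141, with adjusted p = 0.283 with an estimated correlation. The unfolded protein response (0 called, 1 adjusted over the list alone) passed at adjusted p = 0.0461, with adjusted p = 0.0768 with an estimated correlation.

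The number of probe sets called by limma for anac017-2 in water was 115, 97 higher and 18 lower, but 60 without wild type water replicate 1, 40 without anac017-2 water replicate 2, 49 without anac017-2 water replicate 3 and 1891 with array weights. The call of AT2G04050 was lost without any 1 of the 6 arrays, those of AT2G40435, AT2G43535, AT2G34840 and AT4G12540 without any 1 of 5, and those of AT4G16850, AT5G51440 and AT1G53540 without any 1 of 4. The call of AT2G41730 was lost without wild type water replicate 1 or anac017-2 water replicate 2 or 3, that of AT1G21550 without wild type water replicate 3 or anac017-2 water replicate 2, and that of AT5G43450 without wild type water replicate 1. The calls of AT1G71000, AT5G37670, AT2G21640 and UGT73B5 held without any 1 array. Of the 1235 anac017-1 calls and the 115 anac017-2 calls, 52 were shared in the same direction, AT1G71000 and AT1G21550 among them, and 1 in the opposite direction. Independent lists would share 3.6 higher and 0.3 lower probe sets, and the simulations with shared wild type arrays 0. The correlation across probe sets was 0.42, below the 0.48 of the simulations, and the covariance 0.045 beside 0.025. Part of the overlap may come from the shared wild type arrays.

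Under antimycin A, a subset of the transcripts induced in wild type had a lower response in rao2 and anac017-1. AT1G74870 responded by 6.17 ± 0.95 in wild type, and its response was lower by 5.49 ± 1.35 in rao2 (difference -5.49) and by 7.85 ± 1.35 in anac017-1 (difference -7.85). The differences for AT4G16680 were -5.74 ± 0.70 in rao2 and -6.56 ± 0.70 in anac017-1, those for AT2G20720 -5.23 ± 1.05 and -6.65 ± 1.05, and those for AT2G32020 -5.12 ± 1.00 and -4.91 ± 1.00. AT1G71530 differed by -4.96 ± 0.71 and -4.99 ± 0.71, and AT1G03660 by -4.41 ± 0.98 and -5.35 ± 0.98. AT3G54520 differed by -4.41 ± 0.48 and -5.21 ± 0.48, and AT2G18190 (an ATPase-like protein) by -4.16 ± 0.56 and -4.66 ± 0.56. In wild type water AT4G16680, AT2G32020 and AT2G18190 were not above background, and neither were AT4G16680 and AT2G18190 in 2 of 3 antimycin A arrays of rao2 and all 3 of anac017-1. With raised values the differences were -5.62 and -6.36 for AT4G16680, -5.07 and -4.48 for AT2G32020, and -3.95 and -4.35 for AT2G18190. NDB4 rose by at least 3.91 in wild type. It was not above background in any water array, in 2 of 3 antimycin A arrays of rao2 or in all 3 of anac017-1, so its fitted changes there (0.44 ± 0.28 and 0.00 ± 0.28) measure no response. Its differences were -3.74 and -3.9 with raised values (-4.17 ± 0.39 and -4.61 ± 0.39 in the fit). Other transcripts kept their response: STZ had a change of 3.59 ± 0.34 in wild type, 4.16 ± 0.34 in rao2 and 3.97 ± 0.34 in anac017-1, with adjusted p of the difference 0.85 and 0.9. WRKY6 had 2.77 ± 0.26, 2.86 ± 0.26 and 2.95 ± 0.26, with adjusted p of 1 and 0.97 for the difference. In the antimycin A arrays the control signal at the 3' end minus the 5' end was 3.046 to 3.181 in wild type and 3.127 to 3.176 in anac017-2. It was 3.209 to 3.55 in rao2 and 3.287 to 3.686 in anac017-1, without overlap with wild type. Whether RNA quality played a part in the rao2 and anac017-1 differences was not tested.

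In rao2, 3 of 9 stimulon genes had a weaker antimycin A response than in wild type (6 adjusted over the list alone), among them AT2G21640 (-2.98 ± 0.69), with camera adjusted p = 2.88e-11, and adjusted p = 0.0319 with an estimated correlation. NDB4 and NDB2 (-1.72 ± 0.39) were weaker among 5 alternative respiratory genes (2 adjusted over the list alone), with adjusted p = 0.0011, and adjusted p = 0.02 with an estimated correlation. Of 8 heat shock genes AT5G51440 had a lower response (-2.77 ± 0.68, 1 adjusted over the list alone), with adjusted p = 0.0011, and adjusted p = 0.219 with an estimated correlation. The detoxification list had 0 called (3 adjusted over the list alone), with adjusted p = 0.0011, and adjusted p = 0.0583 with an estimated correlation. The rao2 replicates spread widely for some of these genes. The SE and the p-values of the fit pool the spread of all 12 groups, so they do not measure this spread within rao2. AT2G32020 was at 9.39 (log2) in rao2 antimycin A replicate 1 and at 4.62 and 6.18 in replicates 2 and 3, against a wild type mean of 11.98 ± 0.09 (SD, n = 3). AT2G21640 was at 10.87, 7.24 and 7.64 and NDB4 at 3.00, 1.80 and 1.80 in the same arrays, the last 2 not above background.

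Across all probe sets limma called 295 with a different antimycin A response in rao2, 79 higher and 216 lower, and 458 without wild type antimycin A replicate 1. Fitting only the arrays compared gave 34. The call of AT1G74870 was lost without any 1 of 10 of the 12 arrays, those of AT2G21640 and AT5G51440 without any 1 of 7 and that of NDB2 without any 1 of 4. The call of AT1G03660 was lost without rao2 antimycin A replicate 2 or 3.

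In anac017-1, 7 of 9 stimulon genes had a weaker antimycin A response (9 adjusted over the list alone), among them AT2G04070 (-6.07 ± 1.04), AT2G21640 (-5.76 ± 0.69) and AT2G04050 (-5.57 ± 1.35). Camera gave adjusted p = 2.05e-17, and adjusted p = 0.00839 with an estimated correlation. Of 8 heat shock genes 5 had a lower change than in wild type (7 adjusted over the list alone), such as AT5G51440 (-5.21 ± 0.68) and AT5G37670 (-3.83 ± 0.73), with adjusted p = 1.89e-11, and adjusted p = 0.00839 with an estimated correlation. These were mostly falls in anac017-1, where AT5G51440 changed by -3.62 ± 0.48 and AT5G48570 by -2.72 ± 0.35, against 1.59 ± 0.48 and -0.35 ± 0.35 in wild type. The mean of the list was 8.99 ± 0.04 (log2, SD, n = 3) in water and 6.82 ± 0.34 under antimycin A in anac017-1, and 7.94 ± 0.17 and 8.28 ± 0.63 in wild type. In the detoxification list 2 of 5 were weaker, AT2G04050 and AT2G04070 (4 adjusted over the list alone), with adjusted p = 3.49e-05, and adjusted p = 0.00992 with an estimated correlation. NDB4 and NDB2 (-1.79 ± 0.39) were weaker in the alternative respiratory list (2 adjusted over the list alone), with adjusted p = 0.00157, and adjusted p = 0.00839 with an estimated correlation. AT2G21640 of the reactive oxygen list (1 adjusted over the list alone) and GSTU22 of the glutathione transferases (-3.72 ± 0.98, 2 adjusted over the list alone) were weaker, both lists at adjusted p = 0.0438, and adjusted p = 0.202 and 0.124 with an estimated correlation. Flavonoid synthesis passed upward at adjusted p = 0.0438 with 0 called (0 adjusted over the list alone), and adjusted p = 0.272 with an estimated correlation. In all limma called 677 probe sets, 266 higher and 411 lower, with 1485 under array weights and 333 when only the arrays compared were fitted. The call of AT2G04050 was lost without wild type water replicate 1, and that of GSTU22 without wild type antimycin A replicate 3, wild type water replicate 1 or 2, anac017-1 antimycin A replicate 1 or 2, or anac017-1 water replicate 1.

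The rao2 and anac017-1 differences under antimycin A shared 195 probe sets in the same direction, 149 lower in both and 46 higher in both, with 0 in opposite directions. Of the 149, 132 had risen in wild type, 122 were also lower in anac017-2 and 2 were higher there. Independent lists would share 3.9 lower and 0.9 higher probe sets, and the simulations with shared wild type arrays gave a mean and highest overlap of 0. The correlation of the differences across probe sets was 0.69 beside 0.54 in the simulations and the covariance 0.154 beside 0.059, and part of the excess may come from the 6 wild type arrays that both differences used. The overlap was 105 at an adjusted p under 0.01. The rao2 and anac017-2 differences shared 181 probe sets in the same direction and 25 in opposite directions, where independent lists would share 13.7 higher and 24.1 lower, with a correlation of 0.36, below the simulated 0.5, and a covariance of 0.149 beside 0.054. The anac017-1 and anac017-2 differences shared 236 in the same direction and 151 in opposite directions, where independent lists would share 46 higher and 45.8 lower, with a correlation of 0.25, below the simulated 0.51, and a covariance of 0.12 beside 0.056.

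In anac017-2 the antimycin A response was smaller across most of the responding transcripts. The differences from wild type were -7.94 ± 1.34 for AT3G01830, -7.66 ± 0.76 for AT4G22980, -7.15 ± 0.69 for AT1G05575, and -7.10 ± 1.13 for AT2G23270. AT4G22980 (-2.05 ± 0.53) and AT1G05575 (-1.92 ± 0.49) fell in anac017-2. Among transcripts that fell in wild type, AT3G23450 differed by 4.61 ± 1.69, AT5G01790 by 4.34 ± 1.01 and AT4G09500 by 3.84 ± 0.89. AT1G60590, not called in wild type (-1.03 ± 0.68), rose by 2.91 ± 0.68 in anac017-2 and differed by 3.95 ± 0.96. STZ (-2.82 ± 0.48) and WRKY6 (-3.09 ± 0.37), which kept their response in the other mutants, were weaker as well. AT2G32020 rose by 4.26 ± 0.71 in anac017-2. NDB4 rose there in the fit (1.04 ± 0.28), but 1 antimycin A array and all water arrays were not above background, so this value is neither exact nor a bound. Levels not above background entered some of these values, and with raised values the differences were -7.58 for AT4G22980, -7.04 for AT2G23270, 3.98 for AT5G01790, 3.31 for AT4G09500 and -5.01 for AT2G32020.

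Of 9 stimulon genes 8 had a weaker antimycin A response in anac017-2 (9 adjusted over the list alone), such as AT2G32020 (-5.44 ± 1.00), with camera adjusted p = 9.79e-08, and adjusted p = 0.0782 with an estimated correlation. The list mean was 7.99 ± 0.08 (log2, SD, n = 3) in water and 9.55 ± 0.17 under antimycin A in anac017-2, and 5.64 ± 0.27 and 11.35 ± 0.29 in wild type. AT2G21640 (difference -4.06 ± 0.69) was at 11.18 ± 0.19 in water and 12.26 ± 0.14 under antimycin A in anac017-2, and at 7.54 ± 0.35 and 12.68 ± 0.20 in wild type. All 5 detoxification genes had a lower change, led by UGT73B4 (-7.09 ± 0.78), and UGT73B5 fell in anac017-2 (-1.72 ± 0.29). All 5 reactive oxygen genes, such as AT1G19020 (-4.23 ± 0.37), were weaker, and each of these lists had 5 adjusted over the list alone. Their adjusted p were 4.43e-06 and 6.94e-06, and adjusted p = 0.00787 for each with an estimated correlation. Of 8 heat shock genes 6 had a lower change than in wild type (6 adjusted over the list alone), such as AT5G37670 (-5.13 ± 0.73), with adjusted p = 1.34e-05, and adjusted p = 0.0829 with an estimated correlation. The heat shock list itself fell under antimycin A in anac017-2, with 6 of 8 members such as AT1G53540 (-4.24 ± 0.44) fallen (6 adjusted over the list alone) and adjusted p = 1.69e-09, or adjusted p = 0.0349 with an estimated correlation. Its mean was 9.69 ± 0.31 in water and 7.25 ± 0.31 under antimycin A in anac017-2. Photosynthesis genes were higher in 4 of 9 cases, such as ATPC1 (0.79 ± 0.14, 5 adjusted over the list alone), with adjusted p = 0.0277, and adjusted p = 0.41 with an estimated correlation. WRKY6 and WRKY22 were weaker among 4 WRKY genes (2 adjusted over the list alone), with adjusted p = 0.0473, and adjusted p = 0.364 with an estimated correlation. In all limma called 6467 probe sets, 3932 higher and 2535 lower, and 5539 to 7001 without single arrays. The call of AT3G23450 was lost without any 1 of 10 of the 12 arrays.

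**Figure D3:**
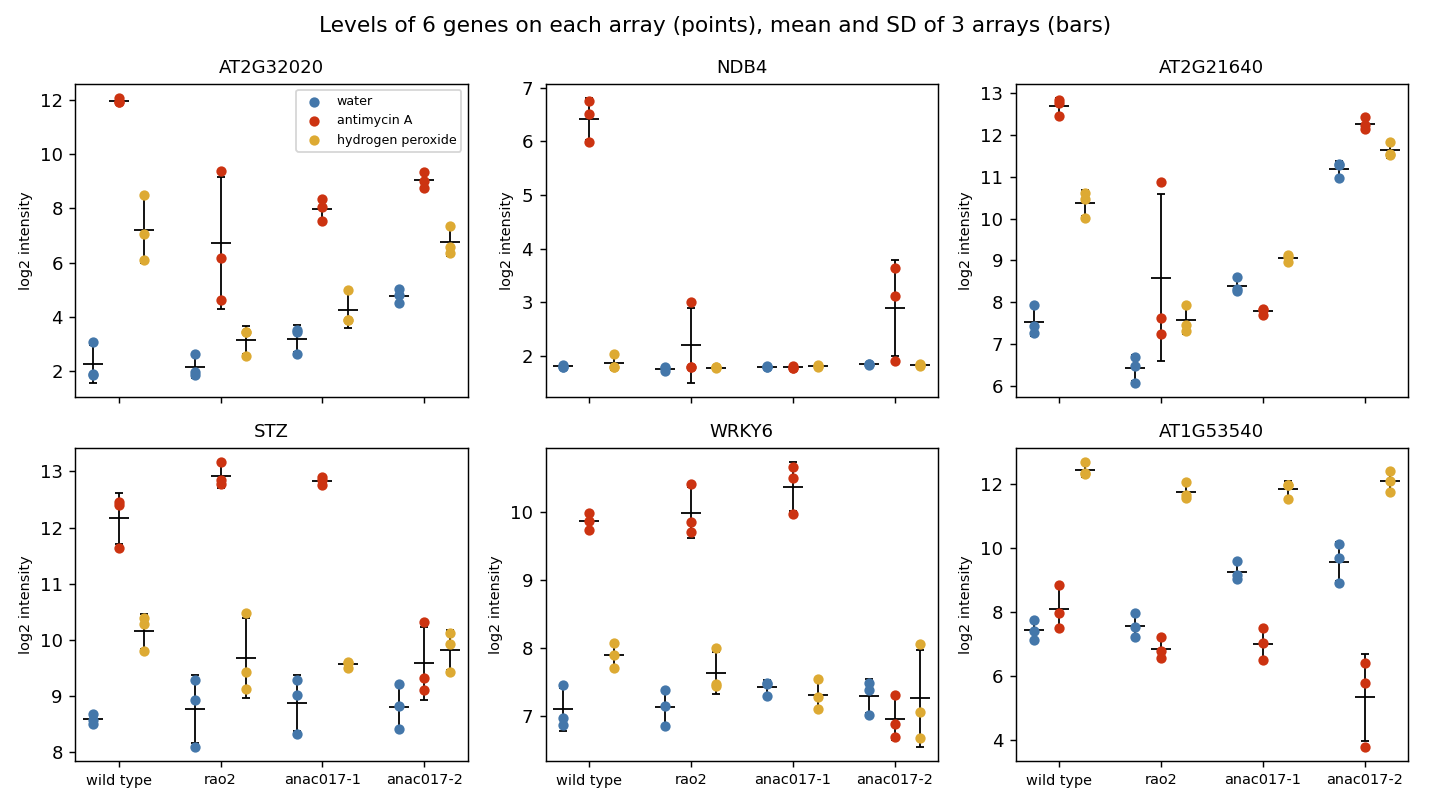
Log2 intensity of 6 transcripts on each array by genotype and spray; points are arrays and bars the mean and SD of 3. Under antimycin A the mean of NDB4 is 6.42 in wild type and 1.79, not above background, in anac017-1, while that of STZ is 12.17 and 12.83.

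Within single genotypes, antimycin A called 9605 probe sets in rao2 (3733 risen, 5872 fallen), 10312 in anac017-1 (4019 and 6293) and 3479 in anac017-2 (1570 and 1909). The last count was 2231 without anac017-2 water replicate 3 and 6441 with array weights. In rao2 the stimulon rose in 7 of 9 genes (8 adjusted over the list alone; adjusted p = 0.000217, and adjusted p = 0.298 with an estimated correlation) and the reactive oxygen list in 5 of 5 (5 adjusted over the list alone; 3.54e-05, and adjusted p = 0.0164 with an estimated correlation). Detoxification (4 of 5, 4 adjusted over the list alone, 0.00456) and WRKY genes (2 of 4, 2 adjusted over the list alone, 0.0231) passed in rao2, with adjusted p = 0.156 and 0.298 with an estimated correlation. In limma camera the heat shock list fell in anac017-1 in 6 of 8 genes (7 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.337 with an estimated correlation). Oxidative phosphorylation fell there in 9 of 14 with 1 risen (10 adjusted over the list alone; 0.0334, and adjusted p = 0.48 with an estimated correlation). Reactive oxygen (4 of 5, 4 adjusted over the list alone, 0.00775), WRKY (2 of 4, 2 adjusted over the list alone, 0.0334) and detoxification genes (3 of 5, 3 adjusted over the list alone, 0.0432) passed upward in anac017-1, with adjusted p = 0.176, 0.337 and 0.337 with an estimated correlation. In anac017-2 the stimulon rose in 3 of 9 genes (3 adjusted over the list alone, adjusted p = 0.000382) and photosynthesis in 2 of 9 (7 adjusted over the list alone, 0.00101), with adjusted p = 0.246 for each with an estimated correlation.

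Across the 3960 probe sets called in wild type for antimycin A with an absolute log2 change of at least 1, the median share of the wild type change was 0.879 in rao2, 0.956 in anac017-1 and 0.179 in anac017-2. Per array the shares averaged 0.88 ± 0.101 (SD, n = 3), 0.952 ± 0.066 and 0.176 ± 0.037. This SD leaves out the spread of the water and wild type arrays, whose means were held fixed. Selection on the wild type values pulls the share of any other genotype below 1, so these values compare the mutants with one another. Of the 3923 risen probe sets, AT2G32020 and NDB4 among them, 166 (4.2%) had a called difference downward, which includes those that fell in the mutant, in rao2, 193 (4.9%) in anac017-1 and 2308 (58.8%) in anac017-2. Of the 6079 fallen, 32 (0.5%), 82 (1.3%) and 3487 (57.4%) had a called difference upward.

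Under hydrogen peroxide, few probe sets were called by limma for a difference of response between a mutant and wild type. This does not show that few responses differed. In anac017-2 the heat shock genes AT5G37670 (-4.16 ± 0.73), AT1G54050 (-3.10 ± 0.45) and the chaperone cofactor gene Fes1A (-1.92 ± 0.35) had a smaller change from water, as did AT5G62730 (-0.99 ± 0.17), and AT3G14490 had a larger one (0.48 ± 0.07). AT5G62730 and AT3G14490 were not above background in 3 of the 4 groups compared, and their raised differences were -0.78 and 0.38. AT5G37670, AT1G54050 and Fes1A were higher in anac017-2 than in wild type in water, by 4.17 ± 0.52, 2.86 ± 0.32 and 1.88 ± 0.25. Under hydrogen peroxide they were at 8.32 ± 0.40, 12.05 ± 0.52 and 11.24 ± 0.64 (log2, SD, n = 3) in anac017-2 and at 8.31 ± 0.46, 12.3 ± 0.33 and 11.28 ± 0.19 in wild type. The genes called in rao2, AT5G62730 (-1 ± 0.17) and AT5G51670 (-1), and those called in anac017-1, AT1G54050 (-2.48 ± 0.45), AT4G30390 (-1.07) and AT3G28270 (2.45), were chosen after their values were seen. So was AT5G41270 (-0.33) in anac017-2. AT5G62730 was not above background in 3 of the groups compared in rao2 and AT3G28270 in both wild type groups, with raised differences of -0.84 and 2.37. In anac017-1 the change of the heat shock list was lower at camera adjusted p = 3.62e-11, and adjusted p = 0.00837 with an estimated correlation, with 0 of 8 genes called (7 adjusted over the list alone), such as AT1G53540 (-2.44 ± 0.62). In anac017-2 this change was lower at adjusted p = 4.8e-15, and adjusted p = 0.0034 with an estimated correlation, with 1 of 8 called (6 adjusted over the list alone). In rao2 its adjusted p was 0.000666, and adjusted p = 0.189 with an estimated correlation, with 0 called (0 adjusted over the list alone). The list mean in water was 7.94 ± 0.17 in wild type, 7.89 ± 0.16 in rao2, 8.99 ± 0.04 in anac017-1 and 9.69 ± 0.31 in anac017-2. Under hydrogen peroxide it was 11.34 ± 0.27, 10.49 ± 0.32, 10.58 ± 0.25 and 11.07 ± 0.45. The control signal at the 3' end minus the 5' end was 3.146 to 3.177 in the wild type hydrogen peroxide arrays, 3.237 to 3.529 in those of rao2, 3.217 to 3.267 in those of anac017-1 and 3.031 to 3.166 in those of anac017-2.

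The change of the stimulon from water to hydrogen peroxide was also lower in all 3 mutants than in wild type, with 0 genes called in each and 1, 5 and 3 adjusted over the list alone in rao2, anac017-1 and anac017-2. Its adjusted p were 0.000136, 3.22e-08 and 4.01e-07, and adjusted p = 0.189, 0.0437 and 0.0725 with an estimated correlation. AT2G21640, for example, had differences of -1.68 ± 0.69, -2.17 ± 0.69 and -2.39 ± 0.69. The level of the list under hydrogen peroxide was 7.76 ± 0.63 in wild type, 5.24 ± 0.09 in rao2, 5.65 ± 0.42 in anac017-1 and 8.59 ± 0.47 in anac017-2, and in water 5.64 ± 0.27, 4.52 ± 0.19, 5.47 ± 0.06 and 7.99 ± 0.08. AT2G21640 was at 11.62 ± 0.17 under hydrogen peroxide in anac017-2 and at 10.37 ± 0.31 in wild type. Detoxification genes also had lower changes, such as UGT73B5 (-1.49 ± 0.41, -1.73 ± 0.41 and -1.99 ± 0.41), which was at 8.97 ± 0.78 under hydrogen peroxide in anac017-2 and 8.90 ± 0.42 in wild type, with 0 called (1, 2 and 2 adjusted over the list alone), with adjusted p of 0.000666, 2.07e-05 and 3.98e-07, and adjusted p = 0.126, 0.0121 and 0.0034 with an estimated correlation. The changes of reactive oxygen genes passed downward in anac017-1 (adjusted p = 4.88e-06) and anac017-2 (0.000226), and adjusted p = 0.00837 and 0.0215 with an estimated correlation, with 0 called and 2 adjusted over the list alone in each. The unfolded protein response passed downward in anac017-1 (0.00653, 1 adjusted over the list alone) and anac017-2 (0.0446, 0 adjusted over the list alone), and adjusted p = 0.0185 and 0.0725 with an estimated correlation. Cell division passed upward in rao2 (0.028, 0 adjusted over the list alone) and anac017-1 (0.0145, 2 adjusted over the list alone), and WRKY genes downward in anac017-1 (0.0243, 0 adjusted over the list alone). With an estimated correlation their adjusted p were 0.218, 0.207 and 0.252.

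In all limma called 3 differences of hydrogen peroxide response in rao2 (0 higher, 3 lower), 6 in anac017-1 (2 and 4) and 8 in anac017-2 (1 and 7). At an unadjusted p under 0.05 it gave 1501, 2217 and 1610 probe sets. The rao2 and anac017-1 calls shared 0 probe sets, where independent lists and the simulations also gave 0, with a correlation of 0.66 beside 0.52 in the simulations and a covariance of 0.089 beside 0.056. Without wild type water replicate 3 the counts were 21, 92 and 20. Without wild type water replicates 1 and 2 the rao2 count was 6 and 1, without wild type hydrogen peroxide replicates 1, 2 and 3 it was 1, 5 and 5, without rao2 hydrogen peroxide replicates 1 and 2 it was 17 and 0, and without rao2 water replicates 1 and 3 it was 6 and 5. The anac017-1 count was 2 and 27 without wild type hydrogen peroxide replicates 2 and 3, and 10 without anac017-1 hydrogen peroxide replicate 3 or any of its water arrays. The anac017-2 count was 3 and 23 without wild type hydrogen peroxide replicates 1 and 3, 5 without wild type water replicate 2, 26, 16 and 55 without its own hydrogen peroxide replicates 1, 2 and 3, and 4 and 5 without its own water replicates 2 and 3. The calls in anac017-2 were lost without any 1 of 6 of the 12 arrays for AT5G37670, 7 for Fes1A and 4 for AT5G62730. Leaving out single arrays left 0 to 21 calls in rao2, 2 to 92 in anac017-1 and 3 to 55 in anac017-2.

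Within single genotypes, hydrogen peroxide called 2596 probe sets in rao2 (1164 risen, 1432 fallen), 323 in anac017-1 (178 and 145) and 2050 in anac017-2 (950 and 1100). ATHSP22.0 rose in each, by 5.75 ± 0.39, 5.02 ± 0.39 and 5.59 ± 0.39, which was at least 5.7 in rao2 and 5 in anac017-1, not above background in water. In limma camera the heat shock list rose in 6 of 8 genes in rao2 (7 adjusted over the list alone, adjusted p = 1.11e-11), in 2 of 8 in anac017-1 (5 adjusted over the list alone, 9.05e-08) and in 2 of 8 in anac017-2 (2 adjusted over the list alone, 0.00239). With an estimated correlation the adjusted p were 0.0107, 0.0786 and 0.433. Reactive oxygen genes rose in 3 of 5 cases in rao2 (5 adjusted over the list alone, adjusted p = 3.42e-05) and in 1 of 5 in anac017-2 (2 adjusted over the list alone, 0.00889), with adjusted p = 0.0107 and 0.325 with an estimated correlation. Photosynthesis passed upward in anac017-1 (0 of 9 called, 1 adjusted over the list alone, 0.0151) and anac017-2 (1 of 9, 3 adjusted over the list alone, 0.00889), with adjusted p = 0.501 and 0.44 with an estimated correlation. The rao2 count was 1377 without rao2 hydrogen peroxide replicate 2. The anac017-1 count was 168 and 116 without its hydrogen peroxide replicates 1 and 2, 129 and 124 without its water replicates 2 and 3, and 1916 with array weights. The anac017-2 count was 952 without its hydrogen peroxide replicate 2, which lay at 9.1 on principal component 1 beside a group mean of 29.6 ± 18.2, and 1192, 1271 and 1014 without its water replicates 1, 2 and 3.

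Across the 699 probe sets called in wild type for hydrogen peroxide with an absolute log2 change of at least 1, heat shock genes such as ATHSP22.0 included, the median share of the wild type change was 0.58 in rao2, 0.36 in anac017-1 and 0.562 in anac017-2. Per array the shares averaged 0.559 ± 0.015 (SD, n = 3), 0.36 ± 0.051 and 0.549 ± 0.09. The water mean of the mutant and the wild type change were held fixed here. This SD therefore leaves out the spread of the water and wild type arrays. Of the 699 probe sets, 0% were called in the opposite direction in any of the mutants. The correlation across them with the wild type change was 0.873, 0.775 and 0.849. Without replicate 1, 2 or 3 of each group the rao2 share was 0.637, 0.653 or 0.434 and the anac017-1 share 0.476, 0.426 or 0.176, and without replicate 3 the anac017-2 share was 0.413.

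**Figure D4:**
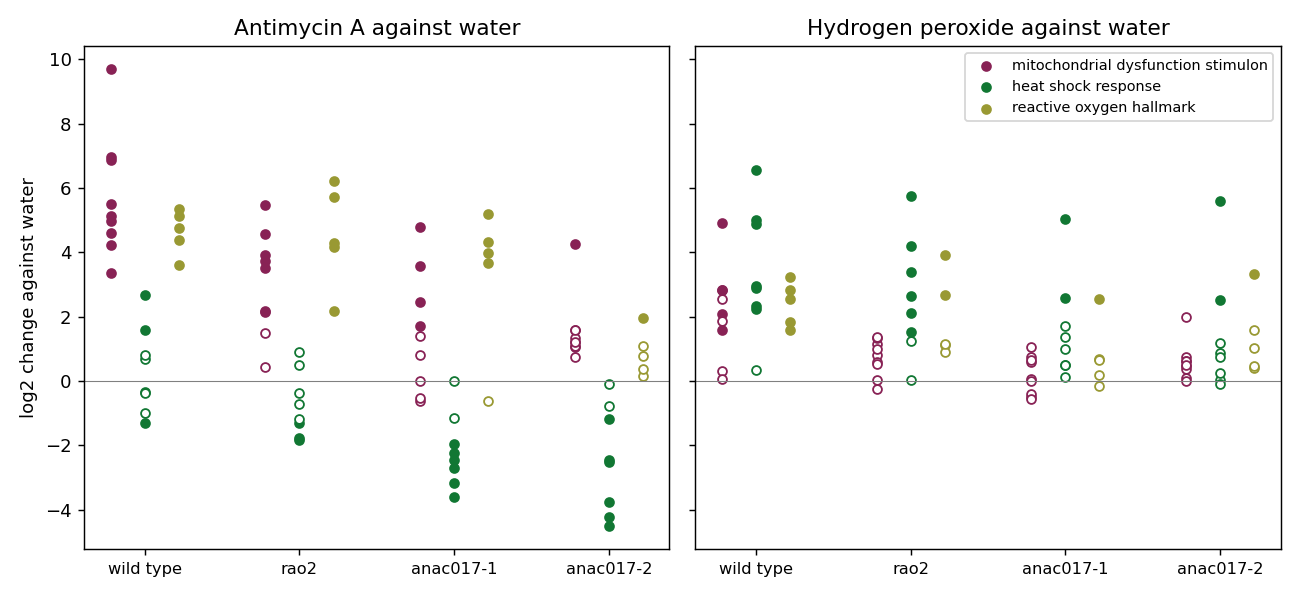
Log2 change against water of each measured member of 3 gene lists, by genotype, under antimycin A (left) and hydrogen peroxide (right); filled points passed limma at an adjusted p under 0.05 and open points did not. The stimulon median is 5.14 under antimycin A in wild type and 1.21 in anac017-2, and the heat shock median 2.93 under hydrogen peroxide in wild type.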

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

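The tests of water or hydrogen peroxide arrays under the antimycin A label, of low values in the wild type water arrays alone and of a larger spread between the anac017-1 arrays were chosen only after the result was seen. The results below were listed because a test of the difference between a mutant and wild type passed in limma (n = 3 per group). Groups of 3 arrays were not tested for outlying samples.

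Differences of antimycin A response numbered 295 in rao2, 677 in anac017-1 and 6467 in anac017-2, and differences of hydrogen peroxide response 3, 6 and 8. The differences of antimycin A response in rao2 and in anac017-1 were -5.49 and -7.85 for AT1G74870, -5.74 and -6.56 for AT4G16680, -5.23 and -6.65 for AT2G20720, and -5.12 and -4.91 for AT2G32020. They were -4.96 and -4.99 for AT1G71530, -4.41 and -5.35 for AT1G03660, -4.41 and -5.21 for AT3G54520, and -4.16 and -4.66 for AT2G18190. In anac017-2 they were 4.61 for AT3G23450, 4.34 for AT5G01790, 3.95 for AT1G60590, 3.84 for AT4G09500, -7.94 for AT3G01830, -7.66 for AT4G22980, -7.15 for AT1G05575 and -7.1 for AT2G23270. The differences of hydrogen peroxide response in anac017-2 were 0.48 for AT3G14490, -4.16 for AT5G37670, -3.1 for AT1G54050, -1.92 for Fes1A and -0.99 for AT5G62730. Levels not above background entered the differences of AT4G16680, AT2G32020, AT2G18190, AT2G23270, AT4G22980, AT5G01790, AT4G09500, AT3G14490 and AT5G62730, so these values are not exact.

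The antimycin A response was smaller in anac017-2 than in wild type. Hydrogen peroxide arrays under that label were argued against by the heat shock list, whose mean on the highest of the 3 arrays lay 2.61 below that of the lowest hydrogen peroxide array (value -2.61), and water arrays by the stimulon list, whose lowest mean lay 1.28 above the highest water array. These tests replaced correlations with the wild type responses, which had not decided the matter (0.371, 0.283 and 0.427 with antimycin A, 0.362, 0.258 and 0.389 with hydrogen peroxide). Higher levels in water were argued against as the source of the whole pattern, since that requires equal levels under antimycin A. There 8852 probe sets differed from wild type, 77 times as many as in water (115), where over 10 was predicted against it. The ratio was 64.9 to 218 without single arrays. Array weighting gave anac017-2 water replicate 2 a weight of 12.12, beside 1.21 and 0.81 for replicates 1 and 3. With these weights the ratio was 5.27 (9962 and 1891), which does not reach 10. In every fit, however, at least 6728 probe sets differed under antimycin A. Recomputing this ratio in other fits was decided after the result was seen. A part played by higher levels in water stays open for the transcripts that were higher there. A weaker exposure to antimycin A may have contributed and stays open, with 2.7% of probe sets called in the opposite direction where under 1% was predicted for it and over 5% against it, and an effect of the genotype stays open as untested.

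More probe sets were higher in water-sprayed anac017-1 than in wild type. Low values in the wild type water arrays alone were argued against, since the median difference against rao2 was 0.884 of that against wild type (0.64 and 0.724). A mild stress of the seedlings could not be decided, with a correlation across probe sets of 0.213 with the wild type hydrogen peroxide response, between the limits of 0.1 and 0.3. RNA quality also stays open: 1 of 3 arrays lay inside the wild type range of the control signal, which met the prediction against it, but by only 0.004 beside an SD of 0.041. An effect of the genotype stays open as untested.

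Hydrogen peroxide called far fewer probe sets in anac017-1 (323) than in wild type (3361). Raised water levels in anac017-1 could account for part of this: measured against the rao2 water arrays, the share of the wild type response kept was 0.527 in anac017-1 and 0.58 in rao2, a ratio of 0.908. A larger spread between the anac017-1 arrays was argued against, with a ratio of residual variances of 0.985. RNA quality was not tested as a source and stays open. The control signal was 3.217 to 3.267 in the anac017-1 hydrogen peroxide arrays and 3.146 to 3.177 in those of wild type. It was higher still, 3.237 to 3.529, in those of rao2, where 2596 probe sets were called. Counts of calls within 2 genotypes do not test a difference between them. The limma test of the difference in hydrogen peroxide response called 6 probe sets in anac017-1. Whether the genotype is the cause of a smaller response stays open.

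Other splits of the same arrays were counted for every contrast. For the contrasts of 2 groups, 1 of 10 splits, the real one, called as many, and 10 splits are too few for a share under 0.05. The real count and the highest other were 10002 and 7 for antimycin A in wild type, 9605 and 148 in rao2, 10312 and 6 in anac017-1, and 3479 and 3 in anac017-2. They were 3361 and 2 for hydrogen peroxide in wild type, 2596 and 15 in rao2, 323 and 7 in anac017-1, and 2050 and 151 in anac017-2. In water they were 30 and 20 for rao2, 1235 and 8 for anac017-1, and 115 and 7 for anac017-2.

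For the difference of antimycin A response in anac017-2, 3 of 100 splits called as many (6467, highest other 6565). This share is under 0.05, which argues against chance without excluding it. The 2 other splits had at most 1 array out of its genotype over both sprays, and splits with 2 out of place called at most 3. For rao2 9 of 100 (295, highest other 837) and for anac017-1 11 of 100 (677, highest other 4830) called as many, so this test does not exclude chance. In all 8 and 10 other splits that did, at most 1 array over both sprays together was out of its genotype, up to an exchange of the labels. The highest other split of each kept the genotypes whole and exchanged their labels in 1 spray. Splits of these kinds keep differences between the genotypes, so the share of splits cannot decide about chance here. Splits with 2 arrays out of place called at most 161 in rao2 and 51 in anac017-1. For hydrogen peroxide, 18 (3, highest other 288), 16 (6, highest other 650) and 10 of 100 splits (8, highest other 182) called as many in rao2, anac017-1 and anac017-2, and chance is not excluded.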

How the results depend on the processing

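Of 444 results for named genes, 317 kept their side of the threshold under every alternative that included their probe set. The dim filter gave no value for the probe sets it left out. Of 6594 alternative values, 0 reversed the direction of a called result, and the direction of uncalled results was not compared. The alternative values lost a call in 281 cases and gained one in 72. With only the compared arrays fitted, 64 named results lost their call, and 54 did so without some array. Fewer arrays leave fewer degrees of freedom in those fits; the cause of the other changes was not tested. The ANAC017 transcript was planned as a result but had no probe set in the gene table, so it was not analysed here and its alternatives were not run. The median level of all values (log2 6.33) was the limit of the dim filter, which left out 9979 probe sets.

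With array weights (0.3 to 12.12) hydrogen peroxide called 5244 probe sets in wild type and 1916 in anac017-1, antimycin A 6441 in anac017-2, and the water contrasts 58 in rao2, 3106 in anac017-1 and 1891 in anac017-2. Weights gave 474 and 1485 differences of antimycin A response in rao2 and anac017-1, and 51, 481 and 60 differences of hydrogen peroxide response in rao2, anac017-1 and anac017-2. With only the arrays of the groups compared, hydrogen peroxide called 737, 91 and 514 in rao2, anac017-1 and anac017-2, and the water contrasts 4, 729 and 71. That fit gave 34 and 333 differences of antimycin A response, and 0 and 32 of hydrogen peroxide response, in rao2 and anac017-1. The dim filter left 1 difference of hydrogen peroxide response in rao2.

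With the replicate block, differences of hydrogen peroxide response numbered 1 in rao2 and 13 in anac017-1, and every other count stayed within 1.5 times. Whether the shared numbers pair the samples is not stated. The mean correlation was 0.039 between arrays of the same number and -0.019 between others. In 4 of 11 comparisons all 3 arrays correlated best with their own number, and in 0 was every pair over 0.1. A weak effect of the replicate number is therefore not excluded.

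With an estimated correlation the list tests passed fell from 7 to 2 for hydrogen peroxide in wild type, 4 to 1 for antimycin A in rao2, 5 to 0 and 3 to 1 for antimycin A in anac017-1 and anac017-2, and 2 to 0 and 3 to 0 for hydrogen peroxide in anac017-1 and anac017-2. In water they fell from 6 to 0 in rao2, 3 to 0 in anac017-1 and 6 to 3 in anac017-2. For differences they fell from 4 to 2, 7 to 4 and 6 to 2 under antimycin A, and from 5 to 0, 7 to 5 and 5 to 3 under hydrogen peroxide, in rao2, anac017-1 and anac017-2. All 3 list calls for antimycin A in wild type held, as did both for hydrogen peroxide in rao2. Leaving out the list members not above background on any array, a choice made after the results were seen, dropped the root marker list. List tests passed then numbered 5 in place of 6 for rao2 in water and 4 in place of 5 for its difference of hydrogen peroxide response. They were 4 in place of 3 for antimycin A in anac017-2, where the auxin list had adjusted p = 0.04, and adjusted p = 0.229 with an estimated correlation. At an adjusted p under 0.01 the overlap of the sprays in wild type was 1355 and that of the rao2 and anac017-1 differences 105. The hydrogen peroxide overlap of these mutants was 1 with quantile normalization. The share kept by rao2 under hydrogen peroxide was 0.626 at a change of at least 2 and 0.608 with the dim filter.

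Leaving out 1 array in turn gave 8933 to 9849 calls for antimycin A in wild type, 8537 to 9363 in rao2, 9500 to 9888 in anac017-1 and 2231 to 2674 in anac017-2. For hydrogen peroxide the ranges were 2100 to 3056, 1377 to 2464, 116 to 337 and 952 to 2260, in the same order. In water they were 29 to 58 in rao2, 641 to 1232 in anac017-1 and 40 to 88 in anac017-2. Differences ranged over 211 to 458, 460 to 800 and 5539 to 7001 under antimycin A, and over 0 to 21, 2 to 92 and 3 to 55 under hydrogen peroxide. The shares kept were computed again without replicate 1, 2 or 3 of every group at once, not without single arrays. Those of rao2, anac017-1 and anac017-2 ranged over 0.839 to 0.897, 0.912 to 0.957 and 0.148 to 0.197 under antimycin A. Under hydrogen peroxide they ranged over 0.434 to 0.653, 0.176 to 0.476 and 0.413 to 0.635.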

Other observations

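The groups in this part were chosen after the data were seen, and the tests of linkage were written before their result. Among 28 gene families with a common symbol and at least 8 measured members, the ATG family of autophagy genes stood out in wild type. Its 8 measured members were ATG3 and genes of the ATG8 group, so the result covers these and not other autophagy genes. Under hydrogen peroxide 7 of 8 rose, among them ATG8H (1.4 ± 0.19, SE of the limma fit, n = 3 per group), ATG8E (1.32 ± 0.39), ATG8F (0.81 ± 0.14) and ATG8B (0.67 ± 0.13), while ATG8D had 0.25 ± 0.10. The camera test gave adjusted p = 1.47e-08, and adjusted p = 0.0107 with an estimated correlation. Under antimycin A 7 of 8 rose as well, with a median of 0.62 and adjusted p = 0.000131, and adjusted p = 0.175 with an estimated correlation. Of 10 VPS genes of endosomal sorting, 5 rose under hydrogen peroxide, such as VPS20.1 (0.69 ± 0.11) and VPS2.1 (0.62 ± 0.12), and VPS2.2 fell (-0.76 ± 0.21), with adjusted p = 0.000134, and adjusted p = 0.0107 with an estimated correlation.

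Under hydrogen peroxide limma called 43 probe sets between anac017-2 and wild type, 691 between rao2 and wild type and 1419 between anac017-1 and wild type. Under antimycin A it called 8852, 1516 and 4242 in the same order. The stimulon list had a mean of 7.57 ± 1.78 (log2, SD, n = 3) in the rao2 antimycin A arrays, from 6.04 to 9.52, and 11.35 ± 0.29 in those of wild type.

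A hypothesis was that variants linked to the ANAC017 locus could account for the differences in water. Among 140 measured loci within 200 annotated genes of ANAC017 on either side, 0 were called in rao2 (17 of 13146 elsewhere), 8 in anac017-1 (698 elsewhere) and 0 in anac017-2 (60 elsewhere). The Fisher exact p was 1, 0.85 and 1, which argues against linkage as a main source of these differences.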
